A study of Mus musculus with 3 samples.

How the data were processed

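Glomeruli of adult mouse kidney were examined by ChIP-seq with an antibody to Foxc1 and another to Foxc2, with 1 library each, plus 1 library of input DNA. Groups were taken from the sample titles. Per the labels' protocols, glomeruli were collected with magnetic beads after perfusion, fixed and sonicated, and the libraries were sequenced on an Illumina instrument. Reads were mapped with Bowtie2 to mm10 and peaks were called with MACS2, per the submitters' processing notes. Their versions and settings, the read filters, the control used for each list and whether material was pooled before calling are not given in the sources used here. The labels do not name replicates, so each list stands for 1 library, and nothing below measures the spread between animals.

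The analysis started from the deposited peak lists. Each gives, per peak, the position, the fold enrichment at the summit (a ratio to the caller's local background, by the authors' peak caller), and the deposited minus log10 of the p-value and of the q-value (−log10). The deposited score column equals 10 times the minus log10 q, with decimals dropped, and was not used. The deposited summit column is an offset in bases from the peak's start. Every peak in both lists had a q-value under 0.05 by the authors' calling. Folds were used to describe, rank and filter peaks within a list, never to compare heights between lists. Depth is unknown, since peak lists give no read counts, and a library sequenced or enriched less can miss weaker sites.

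Gene spans came from the RefSeq table of GRCm38.p6, the same assembly as mm10, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. All gene names of the 20 lists were found in that table, and in the Hippo list 27 names stood for 25 genes, because 2 were older symbols of genes already listed. A genome sequence, strand, exons and transcription start sites were not used here. The planned motif and 7-mer tests, and promoter, exon and intron classes, were therefore not run, and distances planned to start sites were measured to either end of the gene span. A gene was assigned every summit in its span or within 50 kb of either end. Peaks on other sequences, 6 for Foxc1 and 3 for Foxc2, entered only 1 alternative.

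Overlap was counted from 1 shared base pair. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Chance levels came from 1000 seeded random placements of the other list's peaks that kept chromosome and width, between the first gene start and last gene end of the chromosome, with a two-sided empirical p. Assembly gaps were not modelled. Overlap by quartile of fold enrichment was tested by 100000 permutations of quartile labels over peaks. Gene-end shares, within 1 kb, were set against the same kind of placements and compared between lists by Fisher's exact test. For each gene list, the share with a summit was set against 10000 random lists of protein-coding genes of equal size matched on gene-span decile (a permutation of list membership within deciles), with a two-sided empirical p and Benjamini-Hochberg adjustment over 40 tests (20 lists and both antibodies), and a threshold of 0.05. The same test on 8 subsets of peaks (shared, unshared, strong, at and beyond gene ends) was adjusted over 160 tests. The difference between antibodies was tested by 10000 permutations of the list labels over peaks, adjusted over 20 lists. Peaks and genes are not replicates, so these tests describe the libraries and not the factors in other animals. Peaks of both lists were stitched within 10 kb into clusters, as a description.

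The main tests, the gene lists, most alternatives and the rule for naming genes were set before the data were examined, while assignment to gene spans in place of start sites and 4 alternatives were chosen later. Named were the 15 peaks of highest fold in each list with the gene of nearest end, the 10 clusters with the most peaks, up to 8 members with the most peaks of each list past the threshold, up to 3 members of the other lists, and always Foxc1, Foxc2, Wt1, Lmx1b, Tcf21, Nphs1, Podxl and Synpo. The results of 1 list and of 2 further genes of that rule are not reported here, although the list stayed in the adjustment and in the counts of alternatives. The report gives a selection of the list members that this rule names. Alternatives covered the overlap definition, stricter peak thresholds, the chance placement, the distance of assignment, the background of the gene lists, the stitching distance and the ranking value. The alternative with the 2878 strongest Foxc1 peaks left the Foxc2 list as it was, so it could not change a share with Foxc2. Its Foxc2 calls could change only through the shared adjustment and newly drawn random lists.

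The procedures were tested on simulated data, in which peaks other than planted ones were placed uniformly along chromosomes. These simulations do not carry the gene-end preference or the clusters of the real lists, so their error rates do not cover them. With 2878 Foxc2-sized peaks placed at random, 0 of 20 runs called an overlap, and with 20% of peaks planted on Foxc1 peaks, 20 of 20 did. With peaks planted at 50% of the podocyte markers among 21887 genes, the list was called in 50 of 50 runs, and lists with nothing planted had an unadjusted p under 0.05 in 21 of 600 tests (3.5%). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.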

Results

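Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed for the forkhead transcription factors Foxc1 and Foxc2 on kidney glomeruli, the filtering units of the kidney, which hold podocytes, mesangial cells and capillary endothelium. The glomeruli came from C57BL/6 mice aged 8 weeks and were collected with magnetic beads. The labels list 3 libraries, 1 for each antibody and 1 of input DNA, and the series title places the question in the podocyte, the epithelial cell that wraps the glomerular capillaries. The data analysed were 1 peak list per antibody, and the input library was not analysed here. The Foxc1 list held 5213 peaks and the Foxc2 list 2881 peaks, of which 5207 and 2878 lay on chromosomes 1 to 19, X and Y. Median peak widths were 332 bp and 327 bp. The median fold enrichment of a peak over its local background, as the authors' peak caller gave it, was 4.90 in the Foxc1 list (quartiles 4.11 and 6.64, highest 50.5) and 3.97 in the Foxc2 list (quartiles 3.57 and 4.65, highest 16). Sequencing depth is unknown, since the lists carry no read counts. With 1 library per antibody there was no spread between replicates, so every interval and p-value below describes these libraries and covers counting error or random placement only.

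Genes of the podocyte carried peaks of both antibodies far more often than genes of similar length drawn at random. In a permutation test, list membership was shuffled among genes of the same length class, and a gene was counted when a summit lay within its annotated span or within 50 kb of either end. Of 46 podocyte marker genes, 34 had a Foxc1 summit (73.9%, 1.98 times the 37.3% of matched random lists) and 37 had a Foxc2 summit (80.4%, 3.02 times the 26.6% of matched lists). Of 32 genes of the slit diaphragm, the filtering junction between podocyte foot processes, and the podocyte cytoskeleton, 25 had a Foxc1 summit (2.10 times chance) and 24 a Foxc2 summit (2.82 times). Genes mutated in inherited nephrotic syndrome followed with 34 and 30 of 48 (1.93 and 2.36 times). Each of these 6 values had an adjusted permutation p of 0.00114, resting on the smallest p, 0.0002, that 10000 random lists can give. The lists share genes, Plce1 among them, so these values are not independent. Random lists were matched on gene length and not on expression or open chromatin. With Foxc1, lists of housekeeping genes (1.82 times) and mesangial genes (1.99 times) stood about as far above chance as podocyte markers. With Foxc2 they stood at 1.93 and 0.704 times, against 3.02.

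The peak counts of single genes below were not corrected for gene length, and longer genes can collect more peaks by chance. Within the slit diaphragm list, Magi2, a scaffold protein of the slit diaphragm, had 7 Foxc1 and 3 Foxc2 peaks, the strongest at folds of 16.6 and 6.83. It is a long gene (chromosome 5, 19219387 to 20704792). Synpo, which encodes the actin-binding protein synaptopodin, had 6 and 3. Tns2, a focal adhesion protein, had 3 Foxc1 peaks reaching a fold of 36.9 and 5 Foxc2 peaks reaching 4.13. Plce1, a phospholipase C gene mutated in nephrotic syndrome, had 3 and 5, and the junction protein gene Tjp1 had 2 and 5. Inf2, a formin, had 2 and 4, Pard3 had 4 and 2, and Nes had 1 and 4. Among the podocyte markers, Arhgap24, a Rac-regulating GTPase activator, had 5 peaks of each antibody, and Clic5, a chloride channel family member linked to the actin cortex, had 2 of each, at folds of up to 22.5 and 11.5. Pard3b, with a span of 1003618 bp, had 5 and 2 peaks, and Srgap1 had 2 and 4. Col4a3 had 3 and 2, and Vegfa, the vascular growth factor made by podocytes, had 2 and 3. Of the nephrotic syndrome genes, Dlc1 had 6 Foxc1 peaks and 0 Foxc2 peaks, and Myo1e had 3 and 1.

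Genes of the cytoskeleton passed the threshold with both antibodies. Of 37 actin and focal adhesion genes, 27 had a Foxc1 summit (1.97 times chance, adjusted permutation p = 0.00114) and 19 a Foxc2 summit (1.92 times, adjusted p = 0.00582). Itgb5, an integrin beta chain, had 8 peaks of each antibody, 4 of them shared, Parva had 4 of each, and Tns3 had 4 and 3. A list of 28 housekeeping genes also passed, with 14 genes near a Foxc1 summit and 13 near a Foxc2 summit (1.82 and 1.93 times, both adjusted permutation p = 0.0461), Ywhaz and Polr2a among them. That call was lost in 4 of 11 alternative settings for Foxc1, with adjusted p-values of exact or permutation tests from 0.00612 to 0.355, and in 6 of 11 for Foxc2, where they ran from 0.0147 to 1.

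Other lists passed with 1 antibody. For Foxc1 these were podocyte transcription factors (16 of 24, 1.90 times, adjusted permutation p = 0.00667), the glomerular basement membrane and its receptors (18 of 26, 1.74 times, adjusted p = 0.0103) and mesangium and pericytes (18 of 28, 1.99 times, adjusted p = 0.003). The same lists gave 11, 12 and 5 genes with Foxc2 (adjusted permutation p = 0.0994, 0.109 and 0.587), and passed there in 6, 4 and 0 of 11 alternative settings. Foxd1 had 3 Foxc1 and 5 Foxc2 peaks, Dach1 had 3 and 1, and Foxd2 had 0 and 3. In the basement membrane list, Nid1, Itgb1 and Cd151 had Foxc1 peaks with folds of 17.7, 19.1 and 29.5. Among mesangial genes, Fhl2 and Ptn had 5 Foxc1 peaks each, Cald1 had 4 and the transcription factor gene Gata3 had 3, and none of these 4 genes had a Foxc2 peak. Serpine2 had 3 Foxc1 peaks and 1 Foxc2 peak, with 1 Foxc1 peak shared. For Foxc2 the lists were the Hippo pathway with TEAD targets (13 of 25, 1.98 times, adjusted permutation p = 0.0293), with Axl (7 and 2 peaks) and Amotl2 (2 of each), and the forkhead family (20 of 44, 1.92 times, adjusted p = 0.00985), with Foxp1 (7 and 3) and Foxk1 (5 and 2). With Foxc1 these lists gave 14 and 17 genes (adjusted permutation p = 0.1 and 0.245), and passed in 3 and 2 of 11 settings. When list labels were permuted over peaks, none of the 20 lists differed between the antibodies after adjustment. The nearest by permutation were podocyte markers (p = 0.0082, adjusted p = 0.164) and mesangium and pericytes (p = 0.0208, adjusted p = 0.208). With peaks of fold 5 or more alone, the Foxc1 calls of podocyte markers (adjusted permutation p = 0.11, range over alternatives 9.7e-09 to 0.11) and of podocyte transcription factors (adjusted p = 1, range 0.000591 to 1) were lost, the latter also with the 2878 strongest Foxc1 peaks alone (adjusted p = 0.136). So was the Foxc2 call of actin and focal adhesion genes (adjusted permutation p = 0.162, range 0.000667 to 0.162). The Foxc2 calls of the Hippo pathway and the forkhead family were lost there, with a q-value threshold of 1e-05 and with summits counted up to 100 kb away. The Hippo call was also lost without peaks within 1 kb of a gene end (adjusted permutation p = 0.201, range 0.000667 to 0.201). Its ratio to chance with those peaks left out was still 2.15. The ranges given here cover adjusted p-values of exact and permutation tests.

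Genes of tubules and of immune cells stayed at or under the chance level. Of 32 proximal tubule genes, 9 had a Foxc1 summit and 7 a Foxc2 summit (0.902 and 0.88 times chance, both adjusted permutation p = 0.921), Cubn and Slc34a1 among them. Of 26 genes of the distal nephron and collecting duct, 6 and 3 had one (0.751 and 0.453 times, adjusted permutation p = 0.61 and 0.232), Wnk4 with 4 Foxc1 peaks and 1 Foxc2 peak. Of 26 immune cell genes, 3 had a summit of each antibody (0.418 and 0.519 times, adjusted permutation p = 0.144 and 0.341), including Cd4 with 3 Foxc2 peaks. Glomerular endothelium gave 15 and 7 of 32 (1.39 and 0.868 times, adjusted permutation p = 0.234 and 0.921), with Ets1 at 5 and 3 peaks. Parietal epithelium gave 9 and 5 of 18 (1.43 and 1.03 times, adjusted permutation p = 0.349 and 1). Nephron progenitors gave 12 and 6 of 26 (1.47 and 0.92 times, adjusted permutation p = 0.234 and 1), with Notch2 at 2 peaks of each antibody. The TGF-beta and BMP pathway gave 18 and 13 of 33 (1.56 and 1.51 times, adjusted permutation p = 0.0658 and 0.19), with Smad7 and Smad6 among its members. It passed in 7 of 11 alternative settings for Foxc1 and 4 for Foxc2. The Notch pathway gave 11 and 10 of 23 (1.45 and 1.73 times, adjusted permutation p = 0.256 and 0.144), with Maml3 at 8 and 5 peaks. Ribosomal protein genes gave 10 and 12 of 32 (1.28 and 1.72 times, adjusted permutation p = 0.575 and 0.109). Assignment by distance lets neighbours share a peak. The Foxc1 peak near Nphs1 was also the peak counted for the immune gene Tyrobp.

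**Figure D1:**
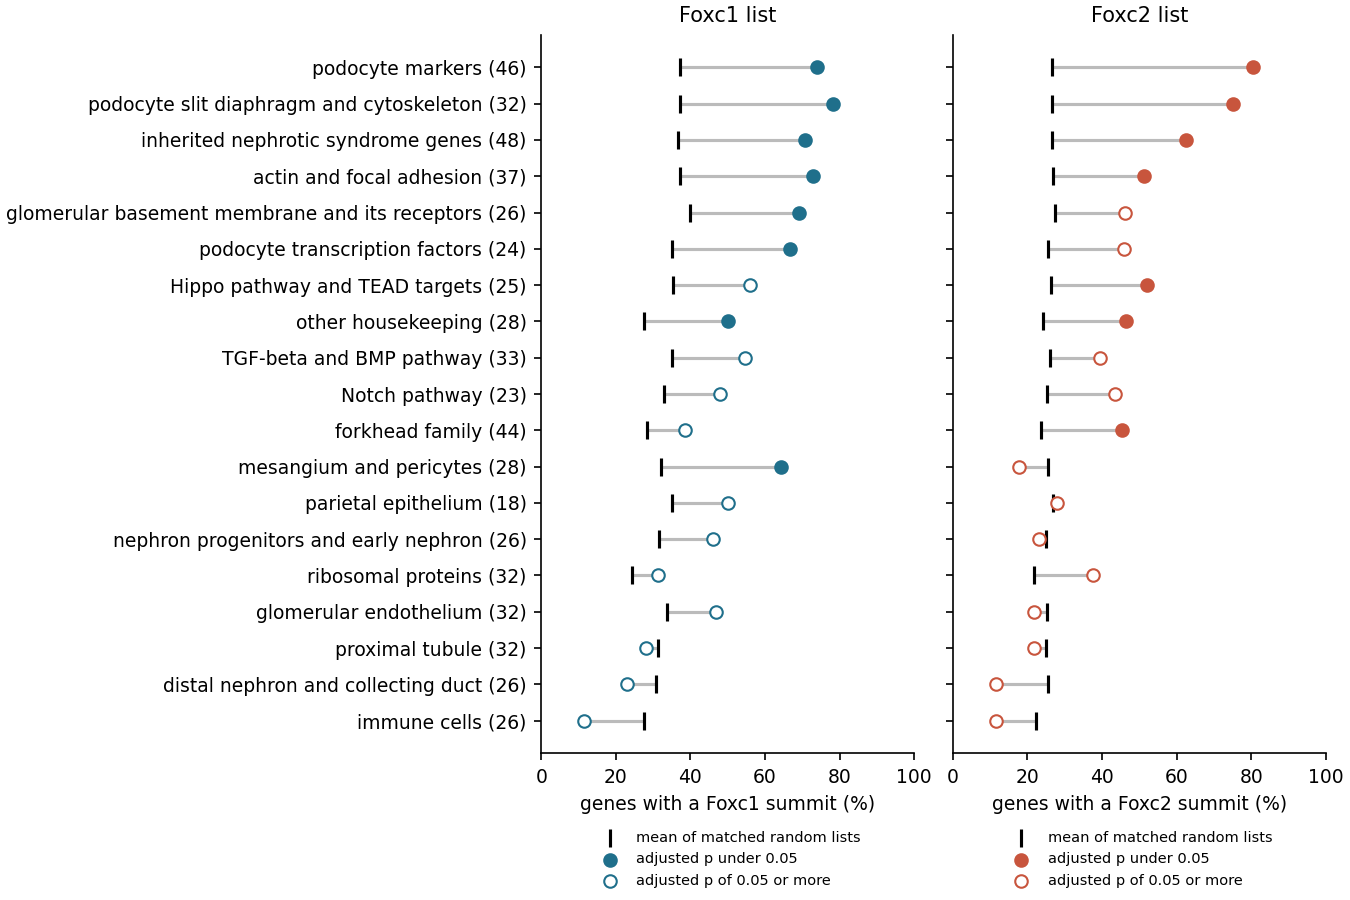
Percentage of the genes of each list with a summit in the gene span or within 50 kb of it, for the Foxc1 list (left) and the Foxc2 list (right); numbers in brackets are genes per list. Circles are the observed percentages, filled where the adjusted p was under 0.05, and vertical ticks the mean of 10000 random lists matched on gene length; podocyte markers stood at 73.9% and 80.4%, immune cell genes at 11.5% in both.

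Of 8 genes always examined, Foxc1, Foxc2, Wt1, Lmx1b, Podxl and Synpo had peaks of both antibodies, Nphs1 had a Foxc1 peak and no Foxc2 peak, and Tcf21 the reverse. Podxl, which encodes podocalyxin on the podocyte surface (chromosome 6, 31519493 to 31563937, mm10), had a Foxc1 peak of fold 11.7 inside the gene, 1.02 kb from one end (31562699 to 31563156). Its Foxc2 peak, of fold 8.60, had a summit 0.063 kb outside the same end (31563723 to 31564204). Lmx1b, a homeodomain factor of podocytes on chromosome 2, had Foxc2 peaks of fold 6.71 and 8.43 inside the gene, more than 35 kb from an end, and 1 of fold 5.16 at 0.23 kb from an end. Its single Foxc1 peak, of fold 4.90, lay 4.66 kb from an end. Wt1 had a Foxc2 peak 0.102 kb from an end and Foxc1 peaks at 2.26 and 9.03 kb. At the gene Foxc1, a Foxc2 summit lay 0.007 kb outside one end and a Foxc1 summit 0.185 kb inside the other. The gene Foxc2 had 1 peak of each antibody, 8.78 and 6.70 kb beyond an end. The same pair of peaks was counted for the neighbouring forkhead genes Foxf1 and Foxl1, named here after their values were seen, and the Foxc1 summit lay within 1 kb of an end of Foxl1. These 3 members of the forkhead list thus rested on 1 peak of each antibody. Nphs1, which encodes nephrin, had a Foxc1 peak of fold 9.33 at 16.5 kb from an end. The only peak of Tcf21 was a Foxc2 peak at 48.4 kb. Synpo alone among the 8 had shared peaks, 2 pairs inside the gene with Foxc1 folds of 3.86 and 5 and Foxc2 folds of 5.33 and 6.86.

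**Figure D2:**
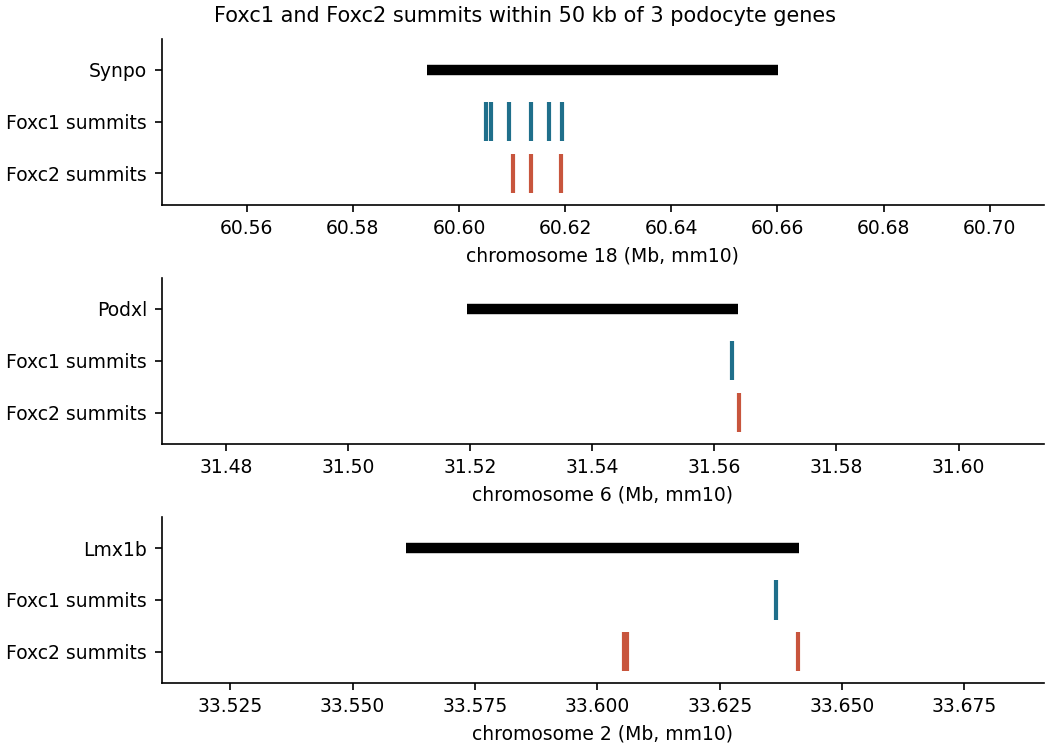
Summits of Foxc1 (blue) and Foxc2 (red) peaks along the mm10 chromosome (x axis, Mb) from 50 kb before to 50 kb after Synpo, Podxl and Lmx1b, each gene span drawn as a black bar (other genes in the windows are not drawn). Synpo held 6 Foxc1 and 3 Foxc2 summits inside the gene, while Podxl and Lmx1b had summits of the antibodies at separate places.

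The peak lists of these related factors shared a small part of their places, yet far more than chance. Of 5207 Foxc1 peaks, 427 were overlapped by at least 1 bp by a Foxc2 peak (8.20%, exact Clopper-Pearson 95% interval 7.47 to 8.98%), 93.8 times the 0.0874% of random placements on the same chromosome (p = 0.002). Of 2878 Foxc2 peaks, 425 were overlapped by a Foxc1 peak (14.8%, exact interval 13.5 to 16.1%), 92.3 times the 0.16% of random placements (p = 0.002, the smallest that 1000 placements can give). With placements that kept each peak's distance class to gene ends, the ratios were 40.3 and 40.5, and with whole lists moved by 50 to 500 kb they were 50.6 and 50.1. Both lists may have been called against the same input library, and no placement models that. The placements do not follow open chromatin either, so any pair of factors in the same cells may exceed this chance level.

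Strong peaks overlapped more often than weak ones. By quartile of fold enrichment, from weakest to strongest, the overlapped share of Foxc2 peaks was 6.94, 8.76, 15.4 and 27.9%, and that of Foxc1 peaks 6.76, 4.53, 7.99 and 13.5% (permutation test over peaks, two-sided p = 1e-05 for both, the smallest it can give). Of the 15 peaks of highest fold in the Foxc1 list, 9 were overlapped. The strongest lay inside Ppard, which encodes a lipid-sensing nuclear receptor (chromosome 17, 28253014 to 28253769, fold 50.5, 20.6 kb from the nearest gene end). It was followed by peaks nearest to Smad7, an inhibitor of TGF-beta signalling (fold 48.3, 9.91 kb), Bcas3 (47.7, 0.45 kb), Zfp212 (46.5, 0.048 kb) and Tmem64 (45.4, 52.5 kb), each with a Foxc2 peak of fold between 4.30 and 6.30 at the same place. Peaks nearest to an end of Iqcd (23 kb, inside Tpcn1), Bahcc1 (1.21 kb), Nrp1 (42.3 kb, inside it) and E130308A19Rik (3.95 kb) were also overlapped. Those nearest to Lnx1 (fold 43.2, 89.4 kb), Syt12 (40.5, 8.13 kb), Atp1b2 (39.2, 2.28 kb), Tinagl1 (38.6, 2.86 kb), Gm44812 (37.8, 647 kb) and Farp1 (37.3, 73.45 kb) were not.

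Of the 15 strongest Foxc2 peaks, 12 were overlapped by a Foxc1 peak. The strongest had its summit 0.016 kb from an end of Smo, the transducer of hedgehog signals (chromosome 6, 29735304 to 29735896, fold 16), and the Foxc1 peak there reached a fold of 29.0. The next were nearest to Nrep (15.6, 0.309 kb), Ccdc54 (13.1, 195 kb), Echdc3 (13.1, 23.6 kb), Hs3st3b1 (13, 109 kb) and Foxd1 (12.3, 9.45 kb from the gene), all overlapped. The peak inside Clic5 (chromosome 17, 44239136 to 44239764) had a fold of 11.5 and its Foxc1 counterpart one of 22.5. Xpnpep1, Snx18, Mast4 and Inppl1 were the nearest genes of other overlapped peaks, while Srgap1 (10.8) and Bcat2 (10.3) were nearest to peaks of Foxc2 alone. Maml3, a Notch coactivator, held 1 peak without a Foxc1 peak (11.9) and 1 with it (10.7).

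**Figure D3:**
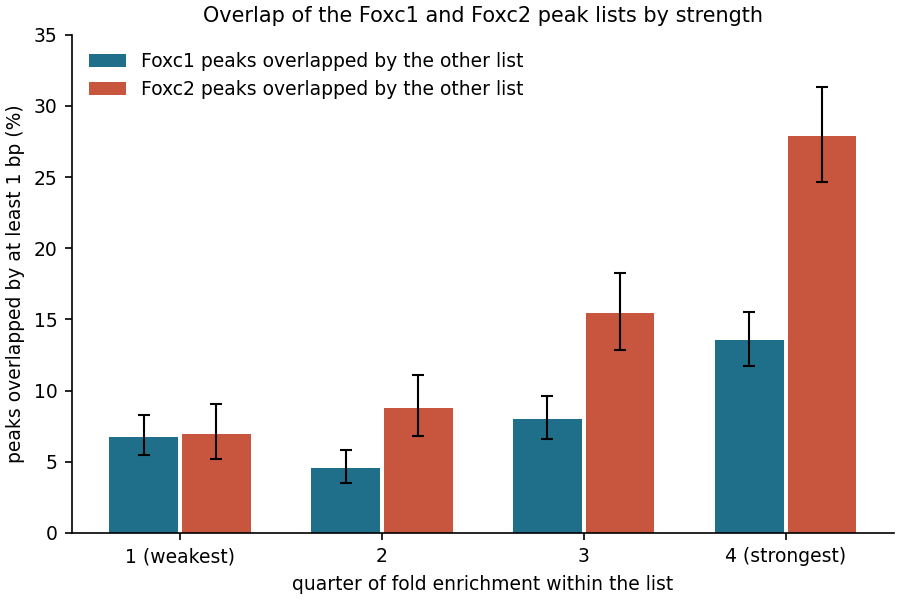
Percentage of peaks overlapped by at least 1 bp by the other list (y axis) in each quartile group of fold enrichment within a list (x axis), for Foxc1 peaks (blue) and Foxc2 peaks (red); error bars are exact 95% intervals for counting error. The share rose to 27.9% in the strongest quartile of the Foxc2 list and to 13.5% in that of the Foxc1 list.

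The antibodies differed in where their peaks lay relative to genes. Of the Foxc2 summits, 1507 (52.4%, exact 95% interval 50.5 to 54.2%) lay within 1 kb of an end of a protein-coding gene, 16.4 times the 3.19% of random placements. Of the Foxc1 summits, 565 did (10.9%, exact 95% interval 10 to 11.7%), 3.47 times chance. The odds ratio between the lists was 9.03. The two-sided p of Fisher's exact test was too small to compute, and its one-sided p, doubled, had a minus log10 of 358. A gene end here is either end of the annotated span, since the annotation used gives no strand, so starts and stops of transcription were not told apart. The median distance to a gene end was 20.8 kb for Foxc1 and 0.797 kb for Foxc2. More than 50 kb from any gene end lay 30.2% of Foxc1 and 12% of Foxc2 summits, against 49.3 and 48.9% by chance. Within gene spans lay 56.4 and 66.3%, against 40.6 and 40.9%. With peaks of fold 5 or more alone, the gene-end shares were 27.8% for Foxc2 and 11.8% for Foxc1.

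**Figure D4:**
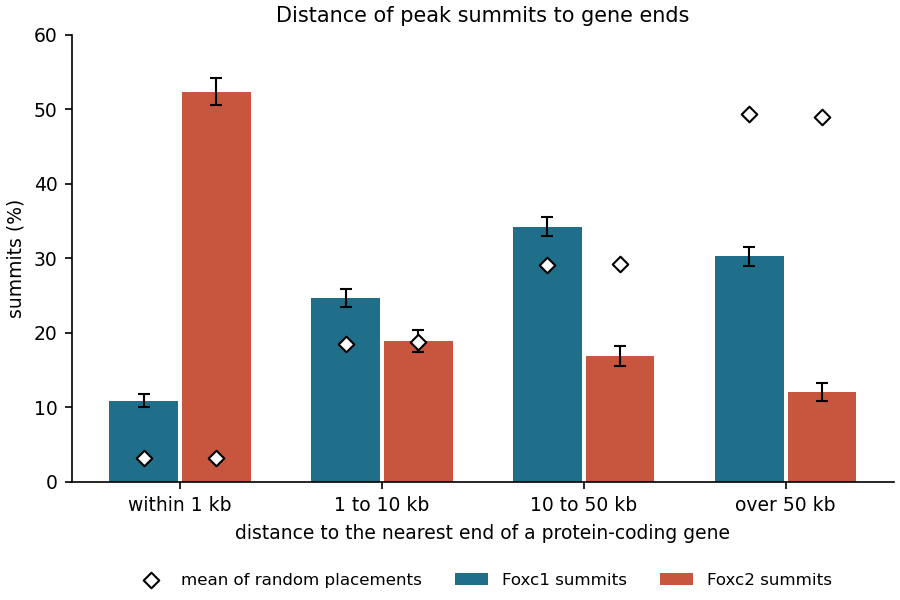
Percentage of summits (y axis) by distance to the nearest end of a protein-coding gene (x axis), for the Foxc1 list (blue) and the Foxc2 list (red), with exact 95% intervals for counting error as error bars; diamonds are the mean of 1000 random placements. Within 1 kb lay 10.9% of Foxc1 and 52.4% of Foxc2 summits.

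Of the 427 Foxc1 peaks overlapped by a Foxc2 peak, 26.7% lay at gene ends (exact 95% interval 22.6 to 31.2%), between the 9.44% of peaks of Foxc1 alone and the 56.7% of peaks of Foxc2 alone. Podocyte markers and slit diaphragm genes stood above matched lists with the Foxc2 peaks beyond gene ends as well, at 26 of 46 and 18 of 32 genes (4.60 and 4.65 times chance, both adjusted permutation p = 0.002).

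Peaks of both lists stitched within 10 kb formed 6548 clusters, of which 83 held 4 or more peaks and 726 held both antibodies. The largest lay on chromosome 6 at 47739602 to 47773139, with 12 Foxc2 peaks of fold 5.80 or less, nearest to the predicted gene Gm40363. The next, at 47654871 to 47686427 on the same chromosome, had 9 Foxc2 peaks and 1 Foxc1 peak over 6 predicted genes. Then came Synpo with 9 peaks over 14.8 kb, Eif4b and Tns2 with 7 over 16.7 kb, Arrb1, which encodes a beta-arrestin, with 7, and Zfp36l1 with 7. Clusters of 6 lay 192 kb from Ccdc54, at Klf9 and at Itgb5, and 1 of 5 at Zbtb16. The number of clusters with 4 or more peaks was 49 with stitching within 5 kb and 156 within 20 kb.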

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

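The tests of peak strength, of housekeeping genes and of other gene classes in this part were chosen after the shares at gene ends had been seen. The overlap at gene ends against elsewhere was also tested only then.

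The gene-end share differed between the antibodies: 52.4% of Foxc2 summits against 10.9% of Foxc1 summits lay within 1 kb of a gene end, a difference of 41.5 percentage points (Fisher's exact test, odds ratio 9.03). Weak peaks near the caller's threshold are argued against as the whole cause, because in the strongest quartile of the Foxc2 list the share was still 31.9% (exact 95% interval 28.5 to 35.5%), although it stood at 65.4% in the weakest quartile. A general signal at the ends of broadly expressed genes was tested with 60 housekeeping and ribosomal genes. Of these, 15% had a Foxc2 summit at an end (5.76% in length-matched lists, permutation p = 0.0124). Of 46 podocyte markers, 43.5% had one (10.3% in matched lists), a larger share by Fisher's exact test (p = 0.00183). That test did not account for gene length, and podocyte markers had the higher chance level. The excess over matched lists was not compared between the groups, so only the raw shares argue against such a signal as the whole cause. Among 84 tubule and immune genes, 0 had one (exact upper limit 4.30%, 7.50% in matched lists, permutation p = 0.0026). An antibody or library property and a property of the transcription factor cannot be told apart, because there was 1 library and 1 antibody for each factor. With Foxc2, mesangial genes (0 of 28, exact upper limit 12.3%, 8.66% in matched lists) and endothelial genes (2 of 32, exact upper limit 20.8%, 8.95% in matched lists) did not stand above chance. The endothelial limit lies above the 15% of housekeeping genes, so an excess there is not excluded. With Foxc1, 5 of 28 mesangial genes (17.9%, 3.26% in matched lists, permutation p = 0.0046) and 2 of 46 podocyte markers (3.21% in matched lists) had a summit at an end. Signal at the ends of active genes may thus remain behind the Foxc2 pattern for podocyte genes, with or without Foxc2 itself. For mesangial genes no such Foxc2 signal was seen.

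Overlapped shares at gene ends against elsewhere differed by 13.4 percentage points for Foxc1 peaks and by -14.8 percentage points for Foxc2 peaks. Nearly the same pairs were counted from both sides, with 114 Foxc1 and 116 Foxc2 overlapped peaks at gene ends. The opposite signs follow largely from the 565 and 1507 peaks there, so they restate the difference in gene-end share and are no separate finding.

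Outside the chromosomes compared, the Foxc1 list held 4 peaks on unplaced sequences and the Foxc2 list 1, and no test was made of these counts.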

How the results depend on the processing

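Of the alternatives, 4 were chosen after seeing the data: leaving out the interior of long genes, a background without receptor and predicted genes, a comparison of podocyte markers with pooled tubule and immune lists, and gene ends among equally many peaks of each list. No paired analysis was possible because each antibody has 1 library, and for the same reason none could be left out. The motif alternatives and the promoter definition that needs strand were not run; 10 kb around the gene body equals the 10 kb assignment used. Overlap above chance, its rise with strength and the gene-end shares kept direction and side of the threshold in every alternative tested. The alternative with all sequences in the lists had no placements of its own and was set against those of the main overlap, without a p-value. The overlapped share ranged from 4.45 to 10.4% for Foxc1 peaks and from 9.52 to 22.5% for Foxc2 peaks. Clusters of 4 or more peaks numbered 49 within 5 kb and 156 within 20 kb against 83, as a longer distance joins more peaks. Lists past the threshold ranged from 7 to 12 for Foxc1 (9 as reported) and from 5 to 12 for Foxc2 (8 as reported), with 5 at summits within 100 kb, 11 within 10 kb and 12 with the gene of nearest end. The share of other housekeeping genes with a Foxc2 summit of fold 5 or more was 3.57%, just under chance and so reversed; the cause was not tested. Of 442 alternative values of gene list shares, 389 stayed on their side of the threshold, 31 newly passed, 21 no longer passed and 1 reversed. Slit diaphragm and nephrotic syndrome genes passed with both antibodies in all 11 settings, and podocyte markers in 11 for Foxc2 and 10 for Foxc1. The setting with the 2878 strongest Foxc1 peaks left the Foxc2 list unchanged, so its Foxc2 shares could not move. Its Foxc2 calls could move only through the shared adjustment and newly drawn random lists, and all 8 were kept. Against the pooled lists, podocyte markers stood at 73.9 against 21.4% for Foxc1 and 80.4 against 15.5% for Foxc2 (Fisher's exact p = 6.9e-09 and 3.7e-13). Depth is unknown, so an absent peak does not show an absent site.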

Other observations

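The tests on the strongest Foxc2 peaks, on mesangial genes, on the copy number of the X chromosome and on small RNA genes were chosen after the results were seen. The tests of neighbouring peaks and of the gene content of the X chromosome were set down after the patterns were noticed and before their own results were computed.

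Many genes had peaks of both antibodies at different places. Of 6404 genes with a Foxc1 summit and 5074 with a Foxc2 summit, 2743 had both, against 1595 if the lists were independent within gene-span deciles, and 2003 of them (73.0%) had no shared peak. Of 46 podocyte markers, 29 had both and 21 of these had no shared peak. Of 28 mesangial and pericyte genes, 15 were near Foxc1 peaks alone, 2 near Foxc2 peaks alone and 3 near both, and of 32 endothelial genes 11, 3 and 4. Neither list differed between the antibodies by permutation (adjusted p = 0.208 and 0.859). A hypothesis is that both factors mark regulatory domains of the same genes at different positions. By this test, 25.6% of the 4780 Foxc1 summits without a Foxc2 peak lay within 50 kb of a Foxc2 summit, against 12.2% in placements that kept the distance class to gene ends (2.11 times, and none of 1000 placements reached the observed share). Those placements do not follow open chromatin, so any pair of factors in the same cells may give such an excess.

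Genes of tRNAs lay near peaks of both antibodies more often than random placements gave. Of 408 tRNA genes, 11 lay within 500 bp of a Foxc1 peak and 20 within 500 bp of a Foxc2 peak, against 1.11 and 0.725 in random placements (both beyond every one of 200 placements). Of 1004 snRNA genes, 10 and 4 did, against 2.69 and 1.59, and only the Foxc1 count was beyond every placement. Counts for 1340 snoRNA genes (2 and 5, against 3.995 and 2.23) and 63 rRNA genes (0 and 1, against 0.21 and 0.12) were not set apart from placements. tRNA genes lie in clusters, so the genes are not independent. These placements kept neither the distance of peaks to gene ends nor open chromatin. The counts therefore do not show binding of either factor to tRNA genes.

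Strong Foxc1 peaks without a Foxc2 peak were common: of 564 peaks of fold 10 or more, 462 had none, and of the 100 strongest Foxc1 peaks 35% were overlapped. In the whole Foxc1 list 4780 of 5207 peaks had none, a larger share. A common set of sites seen with lower sensitivity in the Foxc2 library stays open, because the test made of it, in which 54.0% of the 100 strongest Foxc2 peaks beyond gene ends were overlapped by a Foxc1 peak (exact 95% interval 43.7 to 64.0%), shows peaks of Foxc2 alone and not whether that library could detect the Foxc1 sites. Foxc1 sites in mesangial cells rather than podocytes stay open too, since no sorted cells were analysed here. Of 28 mesangial genes, 5 lay near these strong peaks (17.9%, 4.02 times matched lists, adjusted p = 0.0667), and of 46 podocyte markers, 4 did (8.70%, 1.58 times), which Fisher's exact test could not separate (p = 0.285). Slit diaphragm genes stood at 6 of 32 (3.40 times), podocyte transcription factors at 0 of 24, and the basement membrane list, at 6 of 26, was the only list past the threshold (3.85 times, adjusted permutation p = 0.0338).

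The X chromosome had 32 Foxc1 and 3 Foxc2 peaks, 0.615 and 0.104% of the lists, while it makes up 6.31% of the chromosome length used and 4.41% of the genes. Few genes on the X chromosome do not account for this, since placements that kept the distance class to gene ends put 310 Foxc1 peaks there (2.5th percentile 277). A single copy of the X chromosome in male animals, which would lower signal there, cannot be told apart from other causes, because the labels give no sex, the 3 Foxc1 peaks and 1 Foxc2 peak on the Y chromosome (3.36% of the length) are too few to settle it, and the caller's background on X is not given in the sources used here. Autosomal Foxc1 peaks at 2 times the fold of the weakest peaks would predict 87.6 X peaks, against 32 seen. That lies above the exact Poisson 95% interval of the count (21.9 to 45.2), so the number set for a single copy was missed. At 4 times, a margin added because the background on X is unknown, 19.2 were predicted, under that interval. For Foxc2, 16.5 and 0.515 were predicted, against 3 seen (interval 0.619 to 8.77). A test tried before these, with Foxc1 peaks at 2 times the lowest minus log10 p, predicted 312 and spoke against a single copy as the cause. The answer thus depends on how the loss is modelled.

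The mitochondrial genome held 2 broad peaks in each list, the longest 9161 bp for Foxc1 and 9205 bp for Foxc2, at folds of 2.29 and 2.13. The widest peak on a chromosome was at the same place in both lists, chromosome 1 from 24611622 to 24616123 for Foxc1 (fold 3.87) and from 24611619 to 24616112 for Foxc2 (fold 2.52), over the pseudogenes Gm10222 and Gm10925.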
